A study of Mus musculus with 30 samples.

How the data were processed

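The 30 libraries were strand-specific mRNA libraries (NuGEN Universal plus mRNA-Seq) from 3T3-L1 preadipocytes, in 6 groups of 5: scramble or Kdm5c siRNA, 50 nM, at 24, 48 and 72 h. Per the submitters' processing notes, STAR 2.7.2a, edgeR 3.26.8 and the genome build GRCm38 were used, with no role or order given; the read counter and the annotation are not given in the sources used here. The authors deposited a table of CPM for 55573 genes, and its values were whole numbers of reads divided by the library total, with no further scaling: 100.0% of the nonzero values were within 0.05 reads of a whole number. The second table deposited by the authors is named as normalized counts but held raw counts for 12016 genes. They were equal to the recovered reads in 100.0% of values, and the genes were those with a CPM of at least 1 in 20 or more libraries. Another 20302 genes with reads were in the CPM table only. Every sample column was used, and each column was matched to its sample by day, siRNA and replicate number. Symbols and coordinates came from GENCODE M21 (GRCm38), which held 12010 of the 12016 identifiers.

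Library totals were 25217905 to 33725717 reads, of which the deposited count table held 99.73 to 99.8%. A count of 0 allows up to 3 reads, 0.089 to 0.119 CPM by library; such limits cover counting error only. CPM values are printed as deposited, with mean and SD over 5 libraries.

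The comparisons, tests, alternatives, gene lists and the rule for naming genes were fixed before the data were examined. The plan was limma on log2 CPM, with edgeR in its place should the files hold raw counts; since they did, edgeR 4.0.16 (R 4.3.3) was used, and limma 3.58.1 on log2(CPM + 0.5) became an alternative. A quasi-likelihood model with TMM scaling was fitted to the 12016 genes of the deposited counts, with the full library totals as sizes and 6 group means over all 30 libraries, which left 24 residual degrees of freedom; the common biological coefficient of variation was 0.0367. The low-count filter of edgeR removed 0 further genes. The contrasts were Kdm5c siRNA against scramble on each day, scramble day 0 against day −2, and the difference between the day 0 and day −2 siRNA effects. Tests were two-sided with Benjamini-Hochberg adjustment over the genes of a contrast, and a gene was called at an adjusted p under 0.05. SE is that of the log2 fold change in the edgeR model.

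For gene sets, 37 lists with 1026 symbols were written from textbook knowledge. The 30 lists with at least 5 measured members were tested with camera (limma, through edgeR on negative binomial z-scores of the counts, two-sided, preset correlation 0.01), adjusted over the lists of a contrast, and again with an estimated correlation and with fry. The 7 lists with fewer measured members were not tested as sets; their values are under the other observations. The lists share members with one another, and Kdm5c is itself in the H3K4 list.

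Named genes were Kdm5c and, per siRNA comparison and for the time course, the 8 genes with the largest change each way among called genes with a mean of at least 2 CPM and no overlap between the groups' libraries. For the difference of effects it was 5 each way without the overlap criterion. Predicted gene models, pseudogenes and small RNA genes were left out of the naming; 3 predicted models lay in the range of the genes named on day −2 and 0 in the other ranges. Per list, up to 4 called members with the smallest adjusted p could be named. Some members that this rule would name are not reported here. Other genes are named where a sentence calls for them, such as those set beside the time course, and were chosen after their values were seen.

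Agreement between days was given as Pearson r and Spearman rho of log2 fold changes across 12015 genes, with overlaps of calls against those chance would give. The shared scramble libraries of the time course were handled with 20 simulated sets without an effect. Position along the time course was the projection of a library on the fitted scramble log2 fold changes from day −2 to day 0, with day −2 scramble at 0%. The 3' UTRs of 10911 tested genes were searched for 16301 heptamers, with 100 permutations of the fold changes. The interferon score of a library was its mean log2 CPM (prior count 2) over that list.

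Among the alternatives, limma with pseudocounts of 0.1, 0.5 and 2 and without trend changed the test and the log scale together and used CPM without TMM scaling, and the reads recovered from the CPM table, equal to the counts, changed the genes tested (15135, after the low-count filter of edgeR). DESeq2 1.42.0 changed the test and the scaling together. The others, each changing 1 choice, were no filter (32318 genes), a CPM of at least 5 in 5 libraries, median-of-ratios and upper-quartile scaling, a replicate block, only the libraries of the contrast, and each library left out in turn. Splits of the libraries into other groups of the same sizes, 100 per contrast, were also run. Python work used numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The procedure was tested on simulated data made from the mean levels and fitted dispersions of these libraries, with genes changed 1.25-, 1.5- and 2-fold: edgeR called 86.6%, 92.5% and 100% of them with 11 false calls (5.6% of its calls), and DESeq2 called 86.6%, 94% and 100% with 10 false calls. Camera ranked a list shifted 1.1-fold as number 1, with 0 other lists past the threshold. The simulated genes varied independently, so this does not test camera for lists whose members vary together. The interferon-stimulated genes, for example, had an estimated correlation of 0.87 on day −2. Raw reads were not analysed here.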

Results

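Messenger RNA was sequenced from 3T3-L1 cells, a mouse fibroblast line that can be induced to become adipocytes. The cells had received 50 nM of an siRNA against Kdm5c, which encodes an X-linked histone H3 demethylase, or of a non-targeting siRNA, called scramble here. They were collected 24, 48 and 72 h later, on day −2, day −1 and day 0 counted to the start of differentiation. Each of the 6 groups held 5 libraries, 30 in all. The library totals ran from 25217905 to 33725717 reads, and the group means from 28.08 ± 1.62 to 29.95 ± 3.18 M reads (SD, n = 5). The labels do not say whether the replicates were separate cultures, so each p measures the spread between these libraries, which may be technical. Over the 12016 genes tested, the first principal component held 83.2% of the variance and followed the days, with scramble group means of −46.7, 5.9 and 48. The third component, with 3.1% of the variance, parted the siRNAs on each day, with scramble means of 4.8, 10.5 and 5.6 against −5.9, −5.5 and −9.4.

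The targeted transcript shows how far the knockdown went on each day. Kdm5c (ENSMUSG00000025332; GRCm38 chromosome X, 152233020 to 152274535, plus strand) fell on day −2 from 157.1 ± 1.75 to 25.5 ± 1.29 CPM, read counts scaled to the same library total (SD, n = 5 per group), which left 16.3% of the scramble level. On day −1 it fell from 188.9 ± 2.91 to 35.6 ± 3.57 CPM, with 18.9% left, and on day 0 from 211.7 ± 4.84 to 53.3 ± 2.37 CPM, with 25.2% left. The log2 fold changes were −2.62 (SE 0.04, adjusted p = 4.63e-33), −2.41 (SE 0.04, adjusted p = 1.5e-32) and −1.99 (SE 0.04, adjusted p = 2.34e-30). Every Kdm5c siRNA library lay below every scramble library of its day, and the two-sided exact permutation p of the CPM values was 0.00794 on each day, the smallest that 5 against 5 libraries can give.

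**Figure D1:**
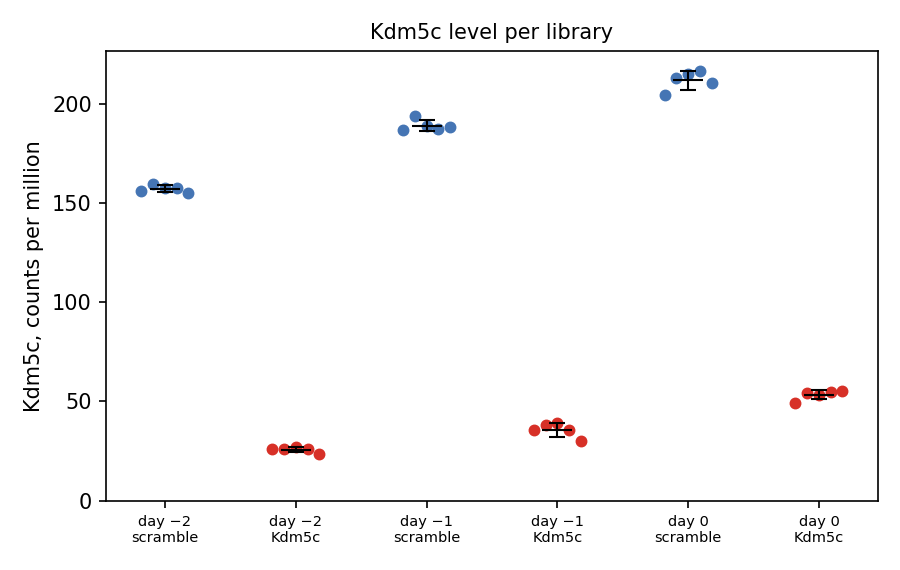
Kdm5c in each library on a linear CPM axis, by day and siRNA; points are libraries and the bars are group means with SD (n = 5). The scramble libraries lie between 154.8 and 216.5 CPM and the Kdm5c siRNA libraries between 23.3 and 55.1 CPM.

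The day −2 comparison asked which transcripts differed 24 h after transfection. Calm3, one of the genes for calmodulin (chromosome 7, 16915379 to 16924114, minus strand), fell from 336.3 ± 3.4 to 127.6 ± 6.31 CPM (SD, n = 5), a log2 fold change of −1.39 (SE 0.03, adjusted p = 4.63e-33). Map4, which encodes a protein that binds microtubules (chromosome 9, 109931460 to 110083955, plus strand), fell from 383.9 ± 4.22 to 165 ± 1.98 CPM (log2 fold change −1.21, SE 0.02, adjusted p = 1.35e-34). Nrn1, the gene for neuritin, fell from 77.5 ± 3.15 to 36.9 ± 0.986 CPM (log2 fold change −1.07). Arf3, a small GTPase of vesicle traffic, the pseudouridine synthase gene Trub1, the GTP-binding protein gene Gem, the dentin matrix protein gene Dmp1 and the pseudokinase gene Trib2 fell by 0.92, 0.90, 0.88, 0.81 and 0.75 on the log2 scale. The 3' UTRs of Calm3, Nrn1, Trub1, Gem and Trib2 held at least 1 of 8 heptamers that went with lower fold changes on this day, and those of Map4, Arf3 and Dmp1 held none. The 8 were chosen from these same fold changes, so their presence in these genes is no separate evidence. Of all searched genes 14.5% held at least 1. The largest increases were smaller than the largest decreases: Ankrd1, a stress-responsive ankyrin repeat gene, rose from 27.6 ± 0.43 to 46.8 ± 1.29 CPM (log2 fold change 0.76, SE 0.06, adjusted p = 4.11e-11). Glipr1 rose by 0.77, Hmgcll1, related to an enzyme of ketone body synthesis, by 0.70, the phosphatidate phosphatase gene Lpin3 by 0.68, Baalc by 0.65, the chemokine gene Ccl9 by 0.63, the surface receptor gene Cd93 by 0.61 and the collagen gene Col11a1 by 0.59 on the log2 scale.

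Of the called genes in lists of sterol, lipid, ribosome and replication genes, more fell than rose on day −2. Of the 25 measured genes of cholesterol biosynthesis, 15 fell, 1 rose and 9 were not called; adjusted over the list alone, 17 fell and 2 rose. Msmo1, a sterol oxidase gene, fell by 0.30 and Srebf2, the transcription factor of the pathway, by 0.14 on the log2 scale. The list's median was −0.14 (camera adjusted p = 7.36e-07, but adjusted p = 0.514 with an estimated correlation). Of 20 genes of fatty acid synthesis, 11 fell, 9 were not called and adjusted over the list alone 12 fell; Fasn fell by 0.16 and Acly by 0.11 (camera adjusted p = 0.00304, adjusted p = 0.514 with an estimated correlation). Of 50 genes of cytosolic ribosomal proteins, 20 fell and 30 were not called, and adjusted over the list alone 23 fell. Rpl27 fell by 0.31, but the median was −0.06 (camera adjusted p = 5.75e-06, adjusted p = 0.577 with an estimated correlation). Of 45 DNA replication genes, 14 fell and 31 were not called, and adjusted over the list alone also 14 fell; Uhrf1 fell by 0.26 and Rfc1 by 0.15 (camera adjusted p = 0.00125, adjusted p = 0.586 with an estimated correlation).

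Among the called matrix and adhesion genes, more rose than fell on day −2. Of 32 measured integrin and focal adhesion genes, 12 rose, 1 fell and 19 were not called, and adjusted over the list alone 13 rose and 1 fell; Itga3 rose by 0.31 and the focal adhesion gene Zyx by 0.20 (camera adjusted p = 0.000893, adjusted p = 0.217 with an estimated correlation). Of 43 matrix glycoprotein genes, 11 rose, 2 fell and 30 were not called, and adjusted over the list alone 12 rose and 2 fell; Ccn4 rose by 0.53 and Ccn5 by 0.32 (camera adjusted p = 0.0024, adjusted p = 0.577 with an estimated correlation). Of 23 collagen genes, 8 rose, 2 fell and 13 were not called, with 9 and 3 adjusted over the list alone. Col7a1 rose by 0.45 (camera adjusted p = 0.0173, adjusted p = 0.608 with an estimated correlation). Of 27 genes of collagen processing, 11 rose and 16 were not called, with 12 higher adjusted over the list alone. Plod2 rose by 0.26 and Serpinh1 by 0.13 (camera adjusted p = 0.00864, adjusted p = 0.577 with an estimated correlation). Of 37 genes of matrix proteases and their inhibitors, 12 rose, 5 fell and 20 were not called, with 13 and 6 adjusted over the list alone. Plau rose by 0.35 and Timp2 fell by 0.17 (camera adjusted p = 0.0198, adjusted p = 0.577 with an estimated correlation).

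Lists of secreted signals and stress genes also passed camera at the preset correlation on day −2. Of 18 measured chemokine and cytokine genes, 6 rose and 12 were not called, with 6 higher adjusted over the list alone. Cxcl12 rose by 0.24 and Ptgs2 by 0.23 (camera adjusted p = 0.00125, adjusted p = 0.217 with an estimated correlation). Of 26 TGF-beta response genes, 10 rose, 2 fell and 14 were not called, the same numbers adjusted over the list alone. Inhba rose by 0.30 and Tgfb2 by 0.32 (camera adjusted p = 0.0202, adjusted p = 0.514 with an estimated correlation). Of 27 genes of the integrated stress response, 8 rose and 19 were not called, with 9 higher adjusted over the list alone. Slc7a11, a cystine transporter gene, rose by 0.50 (camera adjusted p = 0.000893, adjusted p = 0.586 with an estimated correlation). Of 25 genes of protein folding in the endoplasmic reticulum, 14 rose, 3 fell and 8 were not called, with 15 and 3 adjusted over the list alone. The chaperone gene Hspa5 rose by 0.18 and Calr, for calreticulin, fell by 0.52 (camera adjusted p = 0.01, adjusted p = 0.514 with an estimated correlation). Of 42 interferon-stimulated genes, 2 rose and 40 were not called, with 1 higher adjusted over the list alone. Their median was 0.38 (camera adjusted p = 0.00555, adjusted p = 0.745 with an estimated correlation). That list's camera adjusted p was 0.534 without replicate 2 of the Kdm5c siRNA group and 0.105 without replicate 1 of the scramble group. Its median was 0.02 and 0.23 without these libraries, and 0.63 without scramble replicate 5. Other lists also leaned on Kdm5c siRNA replicate 2. Without it the chemokine and cytokine median went from 0.153 to 0.078, and that of the integrated stress response from 0.082 to 0.033.

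In the edgeR test of 12016 genes (two-sided, Benjamini-Hochberg adjusted p under 0.05), 1346 genes rose and 1419 fell on day −2. Only 36 of them changed over 1.5-fold and 4 over 2-fold, and the median size of a called change was 0.15 on the log2 scale. The libraries of the groups did not overlap in 1937 genes, 16.1% of those tested, where chance gives 0.79%. The list of histone H3K4 enzymes, with 2 of 16 members higher, 4 lower and 10 not called (2 and 4 adjusted over the list alone), passed only through Kdm5c: its median was 0.01 while the test read lower (camera adjusted p = 7.36e-07, adjusted p = 0.000204 with an estimated correlation), and without Kdm5c adjusted p was 0.885. In that list Kdm5b rose by 0.17 and Kmt2d fell by 0.21. Of the lists, 15 passed camera with the preset correlation on this day, and 1 of them, the H3K4 list, with an estimated correlation.

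The day −1 comparison asked which transcripts differed 48 h after transfection. Phex, an endopeptidase gene whose loss causes phosphate wasting (chromosome X, 157162075 to 157415312, minus strand), rose from 10.4 ± 0.881 to 25.6 ± 1.1 CPM (SD, n = 5; log2 fold change 1.30, SE 0.07, adjusted p = 6.69e-19). Lsp1, for a protein that binds actin filaments (chromosome 7, 142460809 to 142494867, plus strand), rose from 42.2 ± 1.66 to 97.7 ± 4.09 CPM (log2 fold change 1.21, SE 0.04, adjusted p = 6.61e-29). Hmgcll1 rose by 1.40, Ankrd1 by 1.36, Lpin3 by 1.19, the transcription factor gene Creb5 by 1.18, Glipr1 by 1.13 and Fjx1 by 1.07 on the log2 scale. Calm3 fell from 361.1 ± 8.83 to 146.3 ± 9.26 CPM (log2 fold change −1.30) and Map4 from 436.6 ± 7.5 to 197.8 ± 10.2 CPM (log2 fold change −1.14). Gem fell by 1.1, Arf3 and Nrn1 each by 0.95, and the interferon-inducible gene Ifi27l2a by 1.16 on the log2 scale. Apod, a lipid-binding lipocalin gene, fell from 4.05 ± 0.928 to 1.66 ± 0.487 CPM (log2 fold change −1.31, adjusted p = 0.00272), and Agt, for angiotensinogen, fell by 1.16 on the log2 scale (SE 0.27, adjusted p = 0.0014). Apod and Agt lost their calls when scramble replicates 1, 2 and 3 were left out together (log2 fold changes −1.20 and −0.68, adjusted p = 0.0574 and 0.175).

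Most sterol genes were lower on day −1. Of 25 cholesterol biosynthesis genes, 23 fell, 1 rose and 1 was not called, the same adjusted over the list alone. Mvd fell by 0.42 and Msmo1 by 0.34 (median −0.22, camera adjusted p = 1.97e-13, adjusted p = 0.114 with an estimated correlation). Of 20 fatty acid synthesis genes, 13 fell, 1 rose and 6 were not called, the same adjusted over the list alone. Acaca, for the rate-limiting carboxylase, fell by 0.27, the citrate carrier gene Slc25a1 by 0.28 and the desaturase gene Scd1 by 0.21 (camera adjusted p = 2.01e-06, adjusted p = 0.114 with an estimated correlation). Of 13 measured genes of mature adipocytes, 7 fell and 6 were not called, with 7 lower adjusted over the list alone. The lipid droplet gene Plin4 fell by 0.60 (camera adjusted p = 0.000125, adjusted p = 0.0656 with an estimated correlation). Of 22 adipogenic regulators, 7 fell, 3 rose and 12 were not called, with 8 lower and 3 higher adjusted over the list alone. Stat5a fell by 0.60, Rxra by 0.39 and Ebf2 by 0.28, and Klf5 rose by 0.25 (camera adjusted p = 0.0436, adjusted p = 0.281 with an estimated correlation). The regulators' call was lost without Kdm5c siRNA replicate 1, 4 or 5 (camera adjusted p = 0.0536, 0.0504 and 0.0636) and without scramble replicate 1, 2 or 3 (0.0548, 0.0514 and 0.0713).

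Among the called adhesion and signalling genes, more rose than fell on day −1. Of 32 integrin and focal adhesion genes, 19 rose and 13 were not called, and adjusted over the list alone 21 rose and 1 fell. Itga3 rose by 0.70, the hyaluronan receptor gene Cd44 by 0.29 and the filamin gene Flna by 0.21 (camera adjusted p = 6.61e-07, and adjusted p = 0.0251 with an estimated correlation). Of 26 TGF-beta response genes, 14 rose, 1 fell and 11 were not called, with 15 and 1 adjusted over the list alone. Tagln, a marker of contractile cells, rose by 0.81, Ltbp1, for a protein that holds latent TGF-beta, by 0.45 and the smooth muscle actin gene Acta2 by 0.31 (camera adjusted p = 6.92e-06, and adjusted p = 0.0251 with an estimated correlation). Of 18 chemokine and cytokine genes, 10 rose, 2 fell and 6 were not called, with 11 and 3 adjusted over the list alone. Ccl9 rose by 0.68 and Il11 by 0.62 (camera adjusted p = 0.000179, adjusted p = 0.0656 with an estimated correlation). Of 27 collagen processing genes, 9 rose and 18 were not called, the same adjusted over the list alone. Loxl2 rose by 0.94 (camera adjusted p = 0.00732, adjusted p = 0.634 with an estimated correlation). Of 10 Wnt target genes, 5 rose, 1 fell and 4 were not called, with 6 and 1 adjusted over the list alone. Apcdd1 rose by 0.54 and Ccnd1 by 0.36 (camera adjusted p = 0.0436, adjusted p = 0.22 with an estimated correlation). This call was lost without Kdm5c siRNA replicate 1, 2 or 4 (camera adjusted p = 0.057, 0.0542 and 0.0511) or scramble replicate 1 or 3 (0.0543 and 0.0531).

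Of 50 ribosomal protein genes, 16 fell and 34 were not called on day −1, the same adjusted over the list alone. Rpl27 fell by 0.24 (camera adjusted p = 0.00106, adjusted p = 0.708 with an estimated correlation). Of 46 genes of oxidative phosphorylation, 12 fell, 1 rose and 33 were not called, the same adjusted over the list alone. Cox8a fell by 0.18 (camera adjusted p = 0.0436, adjusted p = 0.656 with an estimated correlation). That call was lost without Kdm5c siRNA replicate 1 or 2 (camera adjusted p = 0.0536 and 0.0832) or scramble replicate 2, 3 or 4 (0.0514, 0.0531 and 0.0655). The H3K4 list again passed through Kdm5c alone: 3 of 16 members rose, 4 fell and 9 were not called, the same adjusted over the list alone, and Setd1b fell by 0.33. Its median was 0.01 where the test read lower (camera adjusted p = 1.9e-06, adjusted p = 0.000438 with an estimated correlation), and without Kdm5c adjusted p was 0.475. In the edgeR test 2254 genes rose and 2014 fell on day −1, 148 of them over 1.5-fold and 20 over 2-fold. Without scramble replicates 1, 2 and 3 together, a setting chosen after the data were seen, 1271 rose and 1284 fell. The libraries did not overlap in 2674 genes, 22.3% of those tested against 0.79% by chance. Of the lists, 12 passed camera with the preset correlation, and 3 of them with an estimated correlation.

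The day 0 comparison asked which transcripts differed at 72 h, on the day differentiation would begin. H19, an imprinted long non-coding RNA (chromosome 7, 142575529 to 142578143, minus strand), fell from 11.6 ± 0.777 to 2.3 ± 0.134 CPM (SD, n = 5), a log2 fold change of −2.33 (SE 0.10, adjusted p = 3.25e-22). Apod fell from 44.9 ± 9.17 to 17.2 ± 1.49 CPM (log2 fold change −1.39, SE 0.16, adjusted p = 2.73e-07). The interferon-inducible genes Iigp1, Ifi27l2a, Gbp9 and Sp100 fell by 1.21, 1.14, 0.97 and 0.95 on the log2 scale; Iigp1 and Gbp9 belong to families of closely related genes, so their counts depend on how shared reads were assigned. The prokineticin receptor gene Prokr1 fell by 0.99 and Calm3 by 0.98, from 332.4 ± 3.15 to 168 ± 2.74 CPM. Phex rose from 12.4 ± 1.12 to 39.5 ± 3.8 CPM (log2 fold change 1.67, SE 0.06, adjusted p = 2.71e-23) and Lsp1 from 47.7 ± 2.34 to 119.3 ± 5.54 CPM (log2 fold change 1.33). The adhesion molecule gene Mcam rose by 1.5, the membrane protein gene Lrrc15 by 1.35, the neurotrophin receptor gene Ntrk3 by 1.33, the intermediate filament gene Nes by 1.29, and Lpin3 and the protease gene Ctsw each by 1.28 on the log2 scale.

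**Figure D2:**
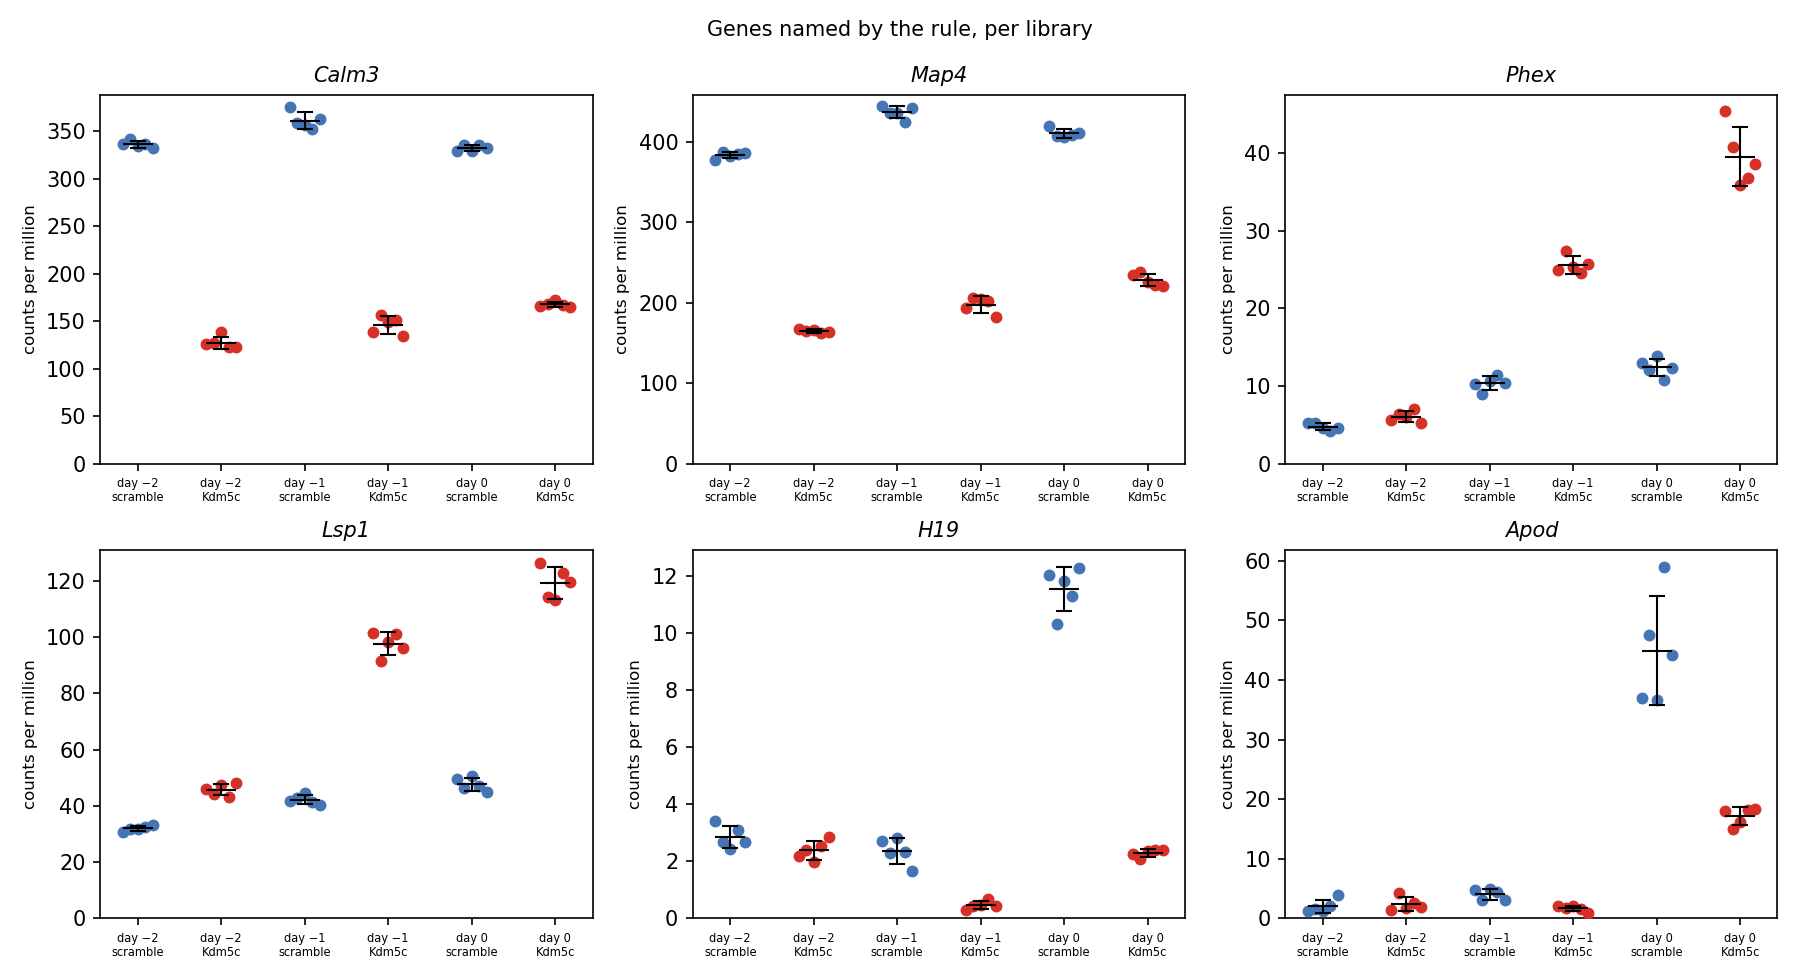
CPM of Calm3, Map4, Phex, Lsp1, H19 and Apod in each library by day, on linear axes; blue points are scramble and red points Kdm5c siRNA libraries, and the bars are group means with SD (n = 5). Calm3 lies lower on each day, and H19 stands at 11.6 against 2.3 CPM on day 0.

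Called adhesion and cell cycle genes rose more often than they fell on day 0. Of 32 integrin and focal adhesion genes, 23 rose, 1 fell and 8 were not called, the same adjusted over the list alone. Itga3 rose by 0.59, Cd44 by 0.42 and Flna by 0.29 (camera adjusted p = 4.49e-10, and adjusted p = 0.00282 with an estimated correlation). Of 64 mitosis genes, 46 rose and 18 were not called, with 53 higher adjusted over the list alone. Ckap2 rose by 0.24 and Cdk1, the kinase that starts mitosis, by 0.22 (median 0.15, camera adjusted p = 1.17e-09, adjusted p = 0.393 with an estimated correlation). Of 22 genes of the G1/S transition, 10 rose, 1 fell and 11 were not called, the same adjusted over the list alone. The cyclin genes Ccnd1 and Ccnd2 rose by 0.41 and 0.28 (camera adjusted p = 0.0128, adjusted p = 0.511 with an estimated correlation). Of 45 DNA replication genes, 14 rose, 1 fell and 30 were not called, the same adjusted over the list alone. Fen1 rose by 0.20 and Pold2 fell by 0.18 (camera adjusted p = 0.0263, adjusted p = 0.63 with an estimated correlation). The replication call was lost without Kdm5c siRNA replicate 1 (camera adjusted p = 0.146) and without scramble replicate 2, 4 or 5 (0.0708, 0.0722 and 0.0617).

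Called genes of secreted factors, folding, collagen processing and bone and cartilage also rose more often than they fell on day 0. Of 18 chemokine and cytokine genes, 11 rose, 1 fell and 6 were not called, the same adjusted over the list alone. Il11 rose by 0.79 and Cxcl12 by 0.38 (camera adjusted p = 2.44e-05, and adjusted p = 0.0443 with an estimated correlation). Of 26 TGF-beta response genes, 8 rose, 1 fell and 17 were not called, the same adjusted over the list alone. Tagln rose by 0.98, Ltbp1 by 0.68 and Acta2 by 0.42 (camera adjusted p = 7.17e-05, and adjusted p = 0.0443 with an estimated correlation). Of 25 folding genes of the endoplasmic reticulum, 15 rose, 6 fell and 4 were not called, with 16 and 6 adjusted over the list alone. Pdia6 and Hspa5 each rose by 0.29 (camera adjusted p = 7.17e-05, adjusted p = 0.12 with an estimated correlation). Of 27 collagen processing genes, 14 rose, 2 fell and 11 were not called, with 16 and 2 adjusted over the list alone. The protease gene Tll1 rose by 1.13 (camera adjusted p = 0.00113, adjusted p = 0.412 with an estimated correlation). Of 5 measured osteogenic and chondrogenic markers, 3 rose and 2 fell, the same adjusted over the list alone. Spp1, for osteopontin, rose by 0.47, Sox5 rose by 0.47, and Dmp1 fell by 0.37 (camera adjusted p = 0.00922, adjusted p = 0.0904 with an estimated correlation).

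In lists of interferon, adipogenesis, adipocyte, ribosome and stress genes, more of the called members fell than rose on day 0. Of 42 interferon-stimulated genes, 12 fell, 1 rose and 29 were not called, the same adjusted over the list alone. Mx1 fell by 0.90 and Stat2 by 0.56, and Ifi27 rose by 0.63 (median −0.46, camera adjusted p = 0.00474, adjusted p = 0.63 with an estimated correlation). Of 23 inhibitors of adipogenesis, 9 fell, 2 rose and 12 were not called, with 10 and 2 adjusted over the list alone. Notch1 fell by 0.56 and Dlk1, the preadipocyte factor, by 0.20 (camera adjusted p = 0.00318, adjusted p = 0.119 with an estimated correlation). Of 13 mature adipocyte genes, 5 fell, 1 rose and 7 were not called, with 6 and 1 adjusted over the list alone. The lipase gene Lipe fell by 0.37 (camera adjusted p = 0.0401, adjusted p = 0.393 with an estimated correlation). The adipocyte call was lost without Kdm5c siRNA replicate 1 (camera adjusted p = 0.0608) or scramble replicate 2, 3 or 5 (0.0532, 0.0519 and 0.0513). Of 50 ribosomal protein genes, 29 fell and 21 were not called, with 34 lower adjusted over the list alone. Rpl19 fell by 0.16 (camera adjusted p = 3.11e-09, adjusted p = 0.393 with an estimated correlation). Of 27 genes of the integrated stress response, 7 fell, 1 rose and 19 were not called, the same adjusted over the list alone. Ddit3 fell by 0.24 and Atf4 by 0.14 (camera adjusted p = 0.00962, adjusted p = 0.63 with an estimated correlation).

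Of 20 fatty acid synthesis genes, 10 fell, 1 rose and 9 were not called on day 0, with 12 and 1 adjusted over the list alone. Gpam, which starts triglyceride synthesis, fell by 0.26 (camera adjusted p = 0.00143, adjusted p = 0.382 with an estimated correlation). Of 25 cholesterol biosynthesis genes, 9 fell, 2 rose and 14 were not called, with 9 and 3 adjusted over the list alone. Msmo1 fell by 0.17 (camera adjusted p = 0.0292, adjusted p = 0.63 with an estimated correlation). That call was lost without scramble replicate 1 or 3 (camera adjusted p = 0.0569 and 0.0742). Of 7 measured mitochondrially encoded mRNAs, 5 fell and 2 were not called, the same adjusted over the list alone. mt-Co1 fell by 0.13 (camera adjusted p = 0.0295, adjusted p = 0.534 with an estimated correlation). It was lost without Kdm5c siRNA replicate 4 (camera adjusted p = 0.0553) or scramble replicate 3 (0.0582). The H3K4 list, with 2 of 16 higher, 5 lower and 9 not called (3 and 5 adjusted over the list alone), passed through Kdm5c (camera adjusted p = 5.01e-06, adjusted p = 0.000798 with an estimated correlation), and without it adjusted p was 0.283. Setd1b fell by 0.32. In the edgeR test 2312 genes rose and 1889 fell on day 0, 209 of them over 1.5-fold and 40 over 2-fold. Libraries did not overlap in 2604 genes, 21.7% of those tested against 0.79% by chance, and 18 lists passed camera with the preset correlation, 4 of them with an estimated correlation.

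**Figure D3:**
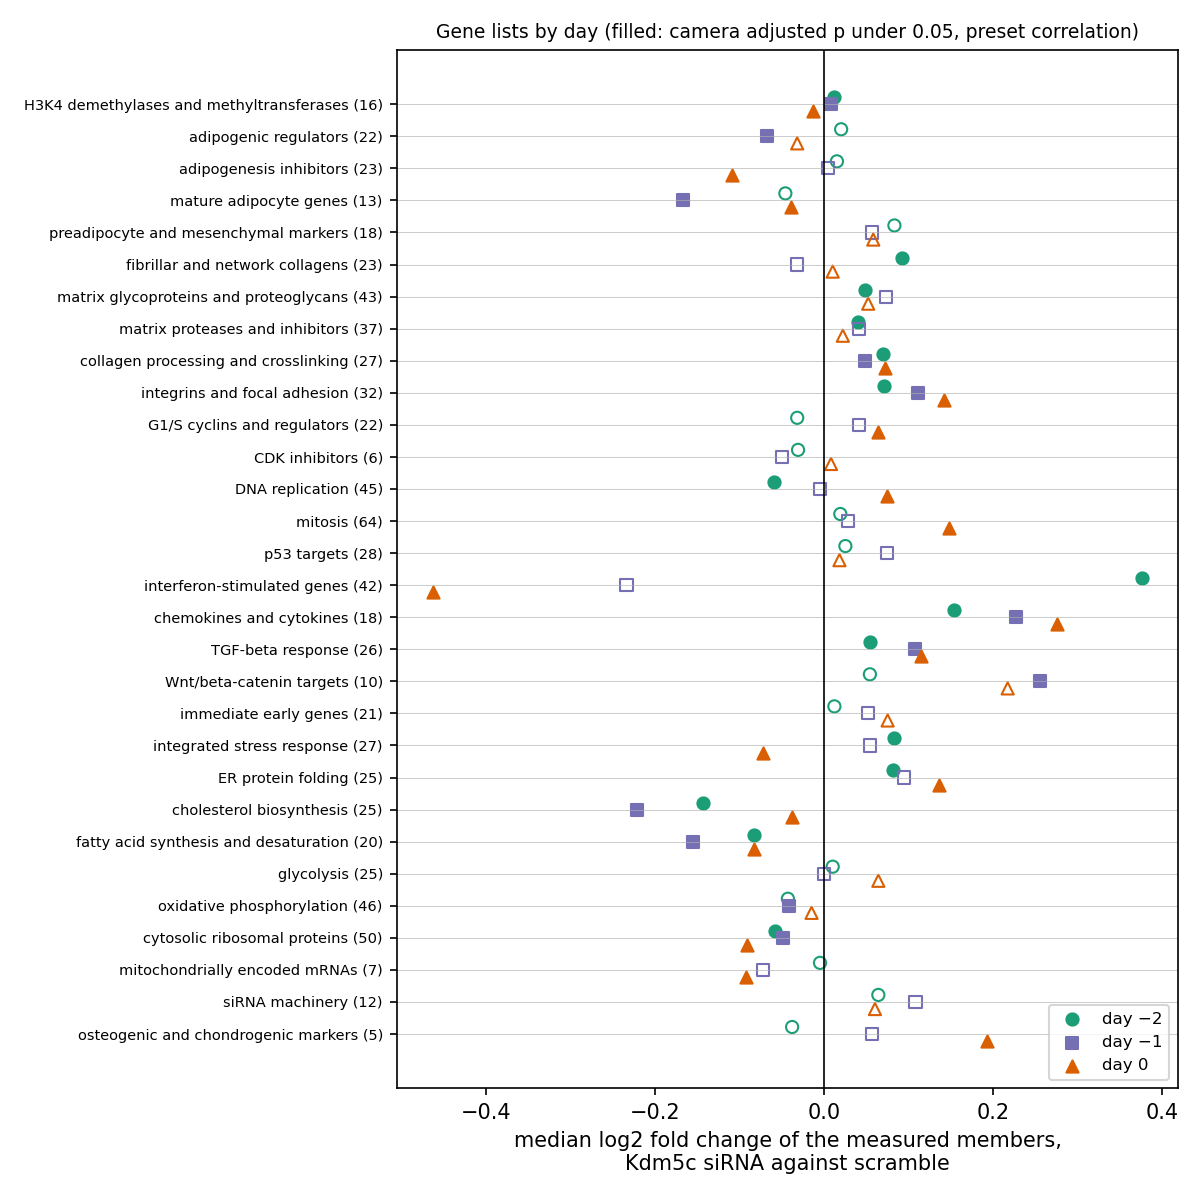
Median log2 fold change of the measured members of each list (number in brackets), Kdm5c siRNA against scramble, by day; filled symbols are lists with a camera adjusted p under 0.05 at the preset correlation, and no error bars are drawn. Cholesterol biosynthesis lies at −0.14, −0.22 and −0.04 from day −2 to day 0, and interferon-stimulated genes lie at 0.38 on day −2 (0.02 without Kdm5c siRNA replicate 2, 0.23 without scramble replicate 1 and 0.63 without scramble replicate 5) and at −0.46 on day 0.

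The lists not past camera on any siRNA day held called members as well. Of 18 preadipocyte and mesenchymal markers, 7, 8 and 6 rose and 2, 5 and 4 fell from day −2 to day 0, with 7, 9 and 7 higher and 2, 5 and 4 lower adjusted over the list alone. Prrx1, a mesenchymal transcription factor gene, fell by 0.26, 0.29 and 0.24, while Ly6a, for the surface antigen Sca-1, rose by 0.34, 0.54 and 0.64 on the log2 scale (camera adjusted p = 0.195, 0.329 and 0.156). Of 28 p53 targets, 10, 11 and 10 rose and 5 fell on each day, with 10, 12 and 10 higher and 6, 5 and 7 lower adjusted over the list alone. Mdm2 rose by 0.12 on day −1 and 0.17 on day 0 (camera adjusted p = 0.189, 0.133 and 0.32). Of 12 genes of the siRNA machinery, 4, 7 and 5 rose and 1 fell, with 4, 8 and 6 higher and 1 lower adjusted over the list alone. Tnrc6c fell by 0.42, 0.48 and 0.37 and Tnrc6a rose by 0.23, 0.19 and 0.18 (camera adjusted p = 0.0515, 0.141 and 0.304). Of 21 immediate early genes, 5, 7 and 7 rose and 2, 1 and 2 fell, with 6, 7 and 7 higher and 3, 1 and 2 lower adjusted over the list alone. Nr4a1 rose by 0.44 on day 0 (camera adjusted p = 0.747, 0.56 and 0.126). Of 6 CDK inhibitor genes, 2, 1 and 2 rose and 3, 3 and 2 fell, the same adjusted over the list alone. Cdkn2b rose by 0.25 on day −1 (camera adjusted p = 0.706, 0.798 and 0.802). Of 25 glycolysis genes, 0, 3 and 10 rose and 1, 4 and 2 fell, the same adjusted over the list alone. The lactate carrier gene Slc16a3 rose by 0.76 on day 0 (camera adjusted p = 0.745, 0.527 and 0.109). The median and the test differed in sign, beside the H3K4 list, for these lists not past camera: adipogenic regulators on day −2 (0.02, test lower), mitochondrially encoded mRNAs on day −2 (0.00, test higher), adipogenesis inhibitors on day −1 (0.00, test lower), osteogenic markers on day −1 (0.06, test lower), collagens on day −1 (−0.03, test higher) and day 0 (0.01, test lower), and CDK inhibitors on day 0 (0.01, test lower).

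The control time course asked what changed in scramble cells over the 48 h from day −2 to day 0, the start of differentiation. These cells went from 24 to 72 h after transfection over the same time, and no untransfected group was included. Effects of culture age and of time since transfection therefore cannot be told apart. Lce1g, a gene of the cornified envelope, fell from 19.97 ± 0.673 to 0.173 ± 0.0796 CPM (SD, n = 5; log2 fold change −6.87, SE 0.12, near the 0.089 to 0.119 CPM that 3 reads make up). Acta1, for skeletal muscle actin, fell from 32.2 ± 1.41 to 0.642 ± 0.225 CPM (log2 fold change −5.68). The receptor gene Lgr6 fell by 4.69, the apolipoprotein gene Apob fell by 4.62, Dynap by 4.54, the anion transporter gene Slco4a1 by 4.35, the LIM domain gene Fhl1 by 4.34 and Tll1 fell by 4.08 on the log2 scale. Col23a1, a transmembrane collagen gene, rose from 0.303 ± 0.144 to 20.9 ± 2.9 CPM (log2 fold change 6.05) and Podn, for a matrix proteoglycan, from 0.203 ± 0.0755 to 10.7 ± 0.849 CPM (log2 fold change 5.65). Ces1a rose by 5.13, the BH3-only gene Bmf by 4.87, Trp63, for a relative of p53, by 4.86, the sterol exporter gene Abcg1 by 4.80, Ptprv by 4.68 and Trim30d by 4.67 on the log2 scale; Ces1a and Trim30d have close neighbours in their gene families, so their counts depend on how shared reads were assigned. Kdm5c itself rose by 0.39 (adjusted p = 1.15e-12). In the edgeR test 5360 genes rose and 5240 fell, 4851 of them over 1.5-fold and 2393 over 2-fold; libraries did not overlap in 9639 genes, 80.2% against 0.79% by chance.

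For each list over the control time course the counts adjusted over the list alone were the same as those over all genes. All 64 mitosis genes fell, Birc5 by 1.85 and Cdk1 by 1.73 on the log2 scale (camera adjusted p = 5.04e-40), and 44 of 45 DNA replication genes fell and 1 rose, with the thymidine kinase gene Tk1 lower by a log2 fold change of −1.97 (camera adjusted p = 3.16e-21). Of 22 G1/S genes, 21 fell and 1 rose, with E2f7 at −2.01 (camera adjusted p = 1.38e-09), and 5 of 6 CDK inhibitor genes rose and 1 fell, Cdkn1a rising by 1.22 (camera adjusted p = 0.00324). Of 28 p53 targets, 17 rose, 5 fell and 6 were not called, Gadd45a rising by 2.57 (camera adjusted p = 0.00245). Of 32 integrin genes, 21 fell, 8 rose and 3 were not called, with the caveolin gene Cav1 at −1.48 (camera adjusted p = 0.000113), and of 26 TGF-beta response genes, 15 fell, 8 rose and 3 were not called, with Id2 at −3.51 and Ltbp1 at −2.25 (camera adjusted p = 0.000607). For these 7 lists adjusted p = 0.0586 with an estimated correlation.

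Of 23 collagen genes, 21 rose, 1 fell and 1 was not called, Col18a1 rising by 1.30 (camera adjusted p = 2.81e-08, adjusted p = 0.194 with an estimated correlation). Of 43 matrix glycoprotein genes, 32 rose, 9 fell and 2 were not called, the fibronectin gene Fn1 rising by 1.42 and Prelp by 3.60 (camera adjusted p = 2.19e-06, adjusted p = 0.27 with an estimated correlation). Of 37 matrix protease genes, 31 rose and 6 fell, Ctsk rising by 2.08 and Adam12 at −2.65 (camera adjusted p = 1.84e-06, adjusted p = 0.113 with an estimated correlation). Of 22 adipogenic regulators, 18 rose, 2 fell and 2 were not called, Zfp423, a factor that commits cells to the adipocyte lineage, rising by 4.00 (camera adjusted p = 0.00426, adjusted p = 0.0955 with an estimated correlation). Of 23 adipogenesis inhibitors, 14 rose, 5 fell and 4 were not called, Notch1 rising by 2.72 (camera adjusted p = 0.00574, adjusted p = 0.113 with an estimated correlation). Of 42 interferon-stimulated genes, 40 rose, 1 fell and 1 was not called, Mx1 rising by 3.11 and Stat2 by 2.07 (camera adjusted p = 0.0354, adjusted p = 0.75 with an estimated correlation).

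Of 25 cholesterol biosynthesis genes, 21 rose, 3 fell and 1 was not called over the time course, Hmgcs1 rising by 0.55 (camera adjusted p = 0.00426, adjusted p = 0.589 with an estimated correlation). Of 25 glycolysis genes, 17 rose, 6 fell and 2 were not called, Pfkp rising by 1.27 (camera adjusted p = 0.0312, adjusted p = 0.629 with an estimated correlation). Of 46 oxidative phosphorylation genes, 39 fell, 3 rose and 4 were not called, with the cytochrome c gene Cycs at −1.59 (camera adjusted p = 0.00255, adjusted p = 0.349 with an estimated correlation). Of 50 ribosomal protein genes, 43 fell, 4 rose and 3 were not called, with Rpl27 at −0.90 (camera adjusted p = 0.00426, adjusted p = 0.629 with an estimated correlation). Of 27 integrated stress response genes, 14 rose, 7 fell and 6 were not called, Vldlr rising by 3.71 (camera adjusted p = 0.0418, adjusted p = 0.667 with an estimated correlation). The stress call was lost without day 0 scramble replicate 1 (camera adjusted p = 0.0734) or day −2 scramble replicate 1 or 3 (0.0526 and 0.0512). None of the 18 lists past camera here passed with an estimated correlation. Among the lists not past camera, the 27 collagen processing genes had a median of 0.10 where the test read lower (15 rose, 11 fell and 1 was not called).

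Whether the siRNA effect was shared between days was read from pairs of days, which have no library in common, over 12015 genes without Kdm5c. Of the genes called on all 3 days, 1266 in number, 633 were higher on each day and 593 lower on each day; Lpin3, Ankrd1 and Lsp1 were among the former and Calm3, Map4 and Arf3 among the latter. Between day −2 and day −1, 952 genes rose on both days where 253 would by chance and 943 fell where 238 would, and 16 went opposite ways. Between day −1 and day 0 these numbers were 1378 against 434, 1143 against 316, and 53, and between day −2 and day 0 they were 705 against 259, 646 against 223, and 141. Pearson r of the log2 fold changes across genes was 0.568, 0.716 and 0.339 (Spearman rho 0.573, 0.643 and 0.351) for these pairs of days, and genes are not independent replicates. With no filter on low values, which adds genes with few reads, r was 0.031, 0.053 and 0.024.

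How the day −1 effect ran along the control time course was compared across the same genes, with no library in common. Tagln, Ltbp1 and Itga3 rose with Kdm5c siRNA on day −1 and fell over the control time course, with log2 fold changes of −3.41, −2.25 and −1.61 there. Plin4, Stat5a and Notch1 fell with Kdm5c siRNA and rose over the time course, by 2.21, 1.56 and 2.72 on the log2 scale. Of 3913 genes called in both comparisons, 27.9% changed in the same direction and 2822 changed in opposite directions; 623 rose in both where 1005 would by chance, and 468 fell in both where 878 would. Pearson r across genes was −0.372 and Spearman rho −0.357, and genes are not independent replicates. Without day −1 scramble replicates 1, 2 and 3 r was −0.2, and with no filter on low values it was −0.092. The day −2 and day 0 effects share scramble libraries with the time course: their r was −0.053 and −0.349, where simulated libraries with no effect gave −0.002 and −0.018. With the shared scramble group divided, 2 libraries to the siRNA effect and 3 to the time course, r was −0.095 and −0.265. The simulated genes varied independently, so drift of whole libraries along the time course is not covered. On day −2 the positions overlapped, at −2.4 to 1.22% with Kdm5c siRNA and −1.09 to 0.53% in scramble.

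**Figure D4:**
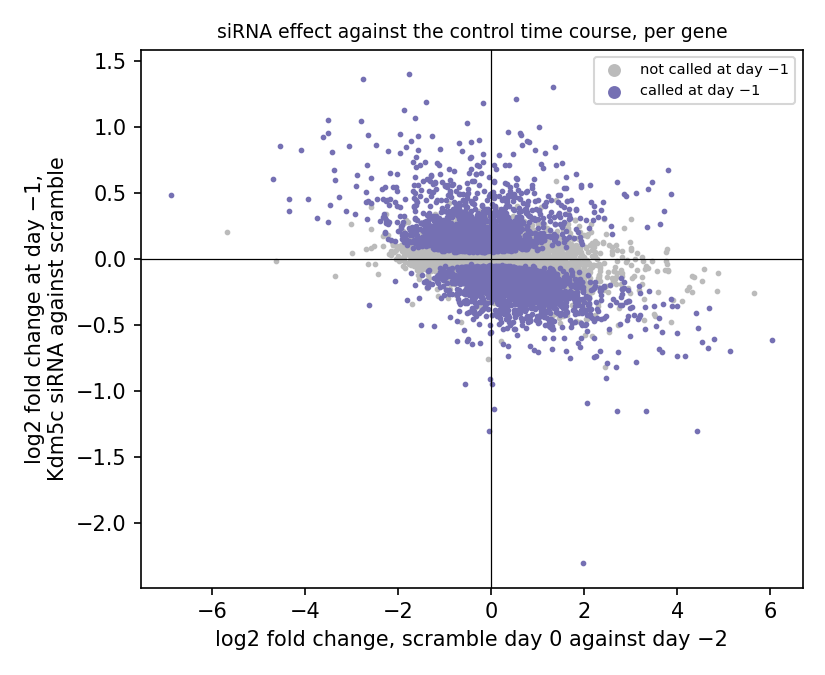
Each point is a gene; the horizontal axis is the log2 fold change of scramble cells from day −2 to day 0 and the vertical axis the log2 fold change on day −1, Kdm5c siRNA against scramble, with genes called on day −1 in purple and others in grey and no error bars. Pearson r across the 12015 genes is −0.372.

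The last comparison asked whether the siRNA effect itself differed between day −2 and day 0. H19 differed most among the named genes: its log2 fold change was lower on day 0 by −2.07 (SE 0.16, adjusted p = 6.91e-13), and that of Apod by −1.63 (SE 0.39, adjusted p = 0.00477). The effect was higher on day 0 for Slco4a1 by 1.41 (SE 0.15), for Lrrc15 by 1.34, for Phex by 1.33 (SE 0.11, adjusted p = 2.79e-11), for Ntrk3 by 1.32 and for Cd53, a tetraspanin gene of leukocytes, by 1.19. For Kdm5c it was higher by 0.63 (SE 0.06, adjusted p = 4.96e-10), the knockdown being weaker on day 0. The interferon-inducible genes Ddx60, Sp100 and Igtp differed by −1.21, −1.19 and −1.16 (adjusted p = 0.0329, 0.0492 and 0.0324). Without day −2 Kdm5c siRNA replicate 2 these adjusted p were 0.131, 0.17 and 0.122. Ddx60 also lost its call without day −2 scramble replicate 1 or 3 (0.0757 and 0.0648), day 0 scramble replicate 4 (0.0562) or day 0 Kdm5c siRNA replicate 3 or 4 (0.0536 and 0.0535). Igtp lost it without day −2 scramble replicate 1, 2 or 3 (0.0687, 0.0602 and 0.063), day 0 scramble replicate 4 (0.0578) or day 0 Kdm5c siRNA replicate 3 or 4 (0.0542 and 0.0519). Sp100 lost it without day −2 scramble replicate 1, 2, 3 or 4 (0.0984, 0.0817, 0.0937 and 0.0524), day −2 Kdm5c siRNA replicate 5 (0.0682), day 0 scramble replicate 1, 3 or 4 (0.066, 0.0657 and 0.0809) or day 0 Kdm5c siRNA replicate 2, 3, 4 or 5 (0.0507, 0.0803, 0.0795 and 0.0753).

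Of 64 mitosis genes, the effect was higher on day 0 for 32 and not called for 32, with 37 higher adjusted over the list alone. Ckap2 differed by 0.26 and Nek2 by 0.37 (camera adjusted p = 4.66e-11, adjusted p = 0.47 with an estimated correlation). Of 45 DNA replication genes it was higher for 18 and not called for 27, with 20 adjusted over the list alone. Uhrf1 differed by 0.33 (camera adjusted p = 1.98e-08, adjusted p = 0.47 with an estimated correlation). Of 22 G1/S genes it was higher for 5 and not called for 17, with 6 adjusted over the list alone. Ccne1 differed by 0.30 (camera adjusted p = 0.000653, adjusted p = 0.47 with an estimated correlation). Of 5 osteogenic and chondrogenic markers it was higher for 4 and lower for 1, the same adjusted over the list alone. Spp1 differed by 0.50, Sox5 by 0.42, Sox9 by 0.37 and Runx2 by −0.20 (camera adjusted p = 1.14e-05, and adjusted p = 0.00779 with an estimated correlation). Dmp1 differed by 0.43 because it fell less, with log2 fold changes of −0.81 on day −2 and −0.37 on day 0. Of 32 integrin genes it was higher for 12, lower for 1 and not called for 19, with 15 and 1 adjusted over the list alone. Cd44 differed by 0.33 (camera adjusted p = 0.000173, adjusted p = 0.168 with an estimated correlation). Of 26 TGF-beta response genes it was higher for 7, lower for 3 and not called for 16, with 8 and 5 adjusted over the list alone. Tagln differed by 0.76 (camera adjusted p = 0.0196, or 0.0517 without day 0 scramble replicate 5, and adjusted p = 0.47 with an estimated correlation).

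Of 27 integrated stress response genes the effect was lower on day 0 for 12 and not called for 15, with 18 lower adjusted over the list alone. Ddit3 differed by −0.34 and Atf4 by −0.21 (camera adjusted p = 2.71e-10, adjusted p = 0.47 with an estimated correlation). Of 42 interferon-stimulated genes it was lower for 6, higher for 1 and not called for 35, with 28 and 1 adjusted over the list alone. The median was −0.91 (camera adjusted p = 1.25e-09, adjusted p = 0.545 with an estimated correlation), and −0.51 without day −2 Kdm5c siRNA replicate 2. Of 23 adipogenesis inhibitors it was lower for 7, higher for 1 and not called for 15, with 8 and 1 adjusted over the list alone. Lrp6 differed by −0.21 (camera adjusted p = 0.0019, adjusted p = 0.168 with an estimated correlation). Of 7 mitochondrially encoded mRNAs it was lower for 2 and not called for 5, with 3 adjusted over the list alone. mt-Co1 differed by −0.15 (camera adjusted p = 0.00456, adjusted p = 0.545 with an estimated correlation).

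Of 23 collagen genes the effect was lower on day 0 for 5 and not called for 18, the same adjusted over the list alone. Col11a1 differed by −1.11 and Col3a1 by −0.34 (camera adjusted p = 0.0196, adjusted p = 0.771 with an estimated correlation). The collagen call was lost without day 0 Kdm5c siRNA replicate 1 (camera adjusted p = 0.0895), day 0 scramble replicate 2 or 5 (0.0618 and 0.0555) or day −2 Kdm5c siRNA replicate 1 (0.0526). Of 50 ribosomal protein genes it was lower for 6 and not called for 44, the same adjusted over the list alone. Rpl10a differed by −0.14 (camera adjusted p = 0.0196, adjusted p = 0.9 with an estimated correlation). The ribosomal call was lost without day 0 Kdm5c siRNA replicate 4 or 5 (0.0514 and 0.0588), day 0 scramble replicate 4 (0.0778), day −2 Kdm5c siRNA replicate 1 or 3 (0.0715 and 0.205) or day −2 scramble replicate 3 (0.11). Of 25 cholesterol biosynthesis genes it was higher for 4 and not called for 21, with 6 adjusted over the list alone. Acat2 differed by 0.19 (camera adjusted p = 0.0422, adjusted p = 0.85 with an estimated correlation). The cholesterol call was lost without day 0 Kdm5c siRNA replicate 4 or 5 (0.0617 and 0.086), day 0 scramble replicate 2, 4 or 5 (0.0665, 0.0685 and 0.0559), day −2 Kdm5c siRNA replicate 2 (0.167) or day −2 scramble replicate 1, 2 or 3 (0.108, 0.0831 and 0.102). In the edgeR test of the difference 1184 genes were higher and 689 lower, 155 of them by over 1.5-fold and 26 by over 2-fold. Of the lists, 13 passed camera with the preset correlation, and 1 of them, the osteogenic and chondrogenic markers, with an estimated correlation.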

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

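The tests chosen only after the result was seen were both tests of the interferon genes, the scaling and position tests of the day −1 effect, and the fits without some of the day −1 scramble libraries.

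Of 146 groups of 5 libraries examined, 13 held a library far from the other 4, where chance sets apart about 1 in 20 groups. On day −2 these were Kdm5c siRNA replicate 5 for Kdm5c (23.3 CPM, others 25.8 to 26.7), Kdm5c siRNA replicate 3 for Calm3 (138, others 123 to 127), scramble replicate 2 for Glipr1 (2.98, others 2.31 to 2.46), Col23a1 (0.556, others 0.211 to 0.284) and Bmf (2.49, others 1.8 to 1.9), and scramble replicate 5 for Abcg1 (0.669, others 0.923 to 0.985). On day −1 it was scramble replicate 1 for Nrn1 (60.2, others 55.3 to 56.6). On day 0 they were scramble replicate 4 for Iigp1 (18.8, others 12.6 to 13.2), Kdm5c siRNA replicate 5 for Prokr1 (6.09, others 4.63 to 4.91), scramble replicate 1 for Apob (0.434, others 0.297 to 0.332) and scramble replicate 3 for Tll1 (3.74, others 2.95 to 3.14). The library total of day 0 Kdm5c siRNA replicate 1 was 30.7 M reads (others 27.6 to 28.3). The mean log2 CPM of the interferon-stimulated genes was 5.35 in day −2 Kdm5c siRNA replicate 2 (others 3.98 to 4.35).

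The siRNA effect differed between day −2 and day 0 in 1873 genes by the edgeR test of the difference. Among the named genes the effect was lower on day 0 for H19 (−2.07 on the log2 scale), Apod (−1.63), Ddx60 (−1.21), Sp100 (−1.19), Igtp (−1.16), Col11a1 (−1.11), Prokr1 (−0.83) and Ccl9 (−0.34). It was higher for Arf3 (0.14), Nrn1 (0.33), Map4 (0.37), Calm3 (0.41), Dmp1 (0.43), Trub1 (0.48), Lpin3 (0.61), Kdm5c (0.63), Trib2 (0.72), Creb5 (0.73), Lsp1 (0.81), Ctsw (0.85), Hmgcll1 (0.85), Nes (0.96), Glipr1 (1.12), Mcam (1.15), Cd53 (1.19), Ntrk3 (1.32), Phex (1.33), Lrrc15 (1.34) and Slco4a1 (1.41). Higher and lower refer to the signed effect. Arf3, Nrn1, Map4, Calm3, Dmp1, Trub1, Kdm5c and Trib2 fell on day −2, so for them a higher effect is a weaker lowering. The calls of Ddx60, Igtp and Sp100 were lost without any of several single libraries, each named with its value in the results, at adjusted p of 0.0535 to 0.131, 0.0519 to 0.122 and 0.0507 to 0.17.

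By camera, 13 lists differed between these days. Their medians were −0.109 for adipogenesis inhibitors, −0.081 for collagens, −0.906 for interferon-stimulated genes, −0.196 for the integrated stress response, −0.022 for ribosomal proteins and −0.088 for mitochondrially encoded mRNAs. They were 0.091 for integrins, 0.117 for G1/S genes, 0.113 for DNA replication, 0.141 for mitosis, 0.032 for the TGF-beta response, 0.092 for cholesterol biosynthesis and 0.418 for osteogenic and chondrogenic markers. The TGF-beta call was lost without day 0 scramble replicate 5 (camera adjusted p = 0.0517). The collagen, ribosomal and cholesterol calls were lost without any of the single libraries named with their values in the results, at camera adjusted p of 0.0526 to 0.0895, 0.0514 to 0.205 and 0.0559 to 0.167. The median of the interferon-stimulated genes was −0.511 without day −2 Kdm5c siRNA replicate 2, that of collagens −0.049 without day 0 Kdm5c siRNA replicate 1, and that of the TGF-beta response 0.064 without day 0 scramble replicate 1. That of ribosomal proteins was −0.035, −0.014, −0.01, −0.04 and −0.036 without day −2 scramble replicate 1 or 3, day −2 Kdm5c siRNA replicate 3 or 4, or day 0 Kdm5c siRNA replicate 2. With an estimated correlation 1 of the 13 lists passed.

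Genes that the deposited count table left out also held signal. Of 3119 such genes, edgeR on the reads recovered from the CPM table called 72 on day −2, 263 on day −1 and 300 on day 0. It called 1844 over the control time course and 68 for the difference between the days.

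A random division of these libraries is argued against for each count of calls: of 100 splits into groups of the same sizes, 1 gave as many calls, the real one. Chance differences between cultures or transfections stay open, since the labels do not say whether the replicates were separate cultures. In fits of only the libraries compared, the real split called 2890 genes on day −2, 4096 on day −1 and 3898 on day 0, and the highest other split called 1 each time. For the time course it called 10549 against 0, and for the difference of effects 1842 against 230.

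The first pattern weighed was the lowering of genes 24 h after transfection: 8 of 16301 heptamers in 3' UTRs scored below every one of 100 permutations, the lowest at −7.27 (CGGGCAA, in 157 genes) against −4.63, and the 8, which overlap one another and form 4 groups, included 6 that lay in the Kdm5c mRNA, as did 28.8% of all heptamers. Part of the lowering may stem from the Kdm5c siRNA acting on other transcripts through its seed, although its sequence is not given in the sources used here. Each of the 8 contains the bases CG, as do the lowest heptamers of day 0, where none scored below the permutations. Scores were adjusted for 3' UTR length and GC content only, so a difference linked with CG-rich genes cannot be told apart from seeds. In other libraries, 38% of the 50 lowest genes of day −1 and 22% of those of day 0 held one of the 8, against 95th percentiles of 22% and 20% in 10000 sets matched on 3' UTR length (one-sided permutation p = 0.0001, the smallest they can give, and 0.0496), but the effects of the days correlate (r 0.568 and 0.339 with day −2), so such an excess would follow whatever its cause, and heptamer scores of day −1 had already been seen. Of all searched genes 14.5% held one of the 8, which were chosen from these same fold changes, against 26.5% of 1363 called lower and 10.6% of 1310 called higher on day −2, and an effect of lower Kdm5c, indirect effects and seeds too weak to be found stay open. The highest score, 5.69 (GGTGCTA) against 5.18 in permutations, met what was written beforehand for seeds of the control siRNA, but the heptamer was afterwards recognised as a miR-29 site, so the control siRNA and miR-29 cannot be told apart.

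The second pattern was the interferon-stimulated genes, whose mean log2 CPM was higher with Kdm5c siRNA on day −2 (4.39 ± 0.56 against 4.05 ± 0.53, SD, n = 5) and lower on day 0 (5.11 ± 0.2 against 5.56 ± 0.15). Variation between these libraries is argued against on day 0, where the two-sided exact permutation p was 0.00794, the smallest possible. It is not argued against on day −2 (0.365) or day −1 (0.198). On day −2 the list's median went from 0.376 to 0.02 without Kdm5c siRNA replicate 2 (0.232 and 0.634 without scramble replicate 1 or 5), below 0.5 of its value (0.188) but not below 0, so 1 library as the cause there cannot be told apart from a difference between the siRNAs. The lower level on day 0 might follow from lower Kdm5c or from unlike responses of the cells to the siRNAs themselves, which the design does not separate. Chance differences between cultures or transfections stay open as well, since the replicates may not be separate cultures.

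The third pattern was the day −1 effect running against the control time course (r −0.372), with the Kdm5c siRNA libraries at 46.8 ± 2.3% and the scramble libraries at 54.1 ± 3% of the way from day −2 to day 0 (SD, n = 5). A shift proportional to the time course is argued against as the only cause. Of 4267 calls, 86.1% kept over 0.5 of their change once the part proportional to the time course was removed. A delay along a course that is not straight was not tested and stays open: in scramble, Peg3 stood at 19.8, 38.9 and 24.6 CPM from day −2 to day 0. Variation in position between libraries is argued against by the two-sided exact permutation p of 0.00794, the smallest possible, yet scramble replicates 1, 2 and 3 stood at 55.9 to 56.7% and replicates 4 and 5 at 50.7 and 51%, and r was −0.2 with 2555 calls without the former and −0.437 with 4311 calls without the latter, in fits chosen by measured position that left 2 or 3 controls. Library size or composition, as 1 factor per library, adds the same amount to every log2 fold change and can neither produce nor remove r, so the scalings (r −0.372 in all 3) were no test, and biases that differ between genes stay open. A slower course of the Kdm5c siRNA cultures could explain a part, 13.9% of the variance if proportional to the time course. Whether such a slowing would come from lower Kdm5c, from the siRNA or from culture density was not tested. Chance differences in position between cultures or transfections also stay open.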

How the results depend on the processing

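The tests chosen only after the data were seen were limma on log2(CPM + 0.5), the counts without genes holding a heptamer, the H3K4 list without Kdm5c, and the fits without day −1 scramble replicates 1, 2 and 3 or 4 and 5.

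The counts of calls on day −2, on day −1, on day 0, over the time course and for the difference of effects (2765, 4268, 4201, 10600 and 1873) stayed within 1.5 times under each alternative but 1. Without day −1 scramble replicates 1, 2 and 3 the day −1 count was 2555, and fewer libraries are part of that setting. DESeq2 called 2749, 4173, 4088, 10551 and 1902 genes, limma on log2(CPM + 0.5) 2799, 4119, 4117, 10603 and 1920, and upper-quartile scaling 2736, 4223, 4216, 10595 and 1891. With no filter (32318 genes) the counts were 2430, 3982, 3951, 13469 and 1696, with a CPM of at least 5 in 5 libraries (10647 genes) 2764, 4112, 4024, 9595 and 1857, and with recovered reads (15135 genes) 2636, 4337, 4335, 12420 and 1815. Without the genes holding a heptamer found on day −2 the siRNA counts were 2265, 3523 and 3488 of 10439, among them genes whose 3' UTR was not searched. Leaving out each library in turn gave 2293 to 2649, 3731 to 4195, 3758 to 4299, 10492 to 10527 and 1606 to 2158. No alternative moved the median of all genes by over 0.1 on the log2 scale.

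The log2 fold change of Kdm5c stayed past the threshold under each alternative run. Leaving out each library in turn gave −2.635 to −2.587 on day −2, −2.444 to −2.349 on day −1 and −2.004 to −1.958 on day 0.

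The lists past camera over the 3 siRNA comparisons, 45 in number, became 8 with an estimated correlation, those of the time course went from 18 to 0 and those of the difference from 13 to 1. The cause was not tested. With fry, which tests each list by itself and not against the other genes, 60, 29 and 13 lists passed, and with Kdm5c left out of the H3K4 list 42 passed for the siRNA comparisons. Leaving out each library gave 42 to 47, 17 to 18 and 10 to 14 lists.

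Pearson r of day −2 with day −1, day −1 with day 0 and day −2 with day 0 was 0.031, 0.053 and 0.024 with no filter on low values and 0.36, 0.519 and 0.214 with the recovered reads, against 0.568, 0.716 and 0.339. The r of the day −1 effect with the time course was −0.092 with no filter, against −0.372. These settings add genes with few reads by construction. For day −1 with day 0, r was 0.746 with a CPM of at least 5 and rho was 0.643; the cause was not tested. Without day −1 scramble replicates 1, 2 and 3 the r with the time course was −0.2, and without replicates 4 and 5 it was −0.437; the cause was not tested. Leaving out each library gave 0.516 to 0.612, 0.697 to 0.724 and 0.279 to 0.408 for the pairs of days and −0.402 to −0.336 for the time course.

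Among 659 results for single genes and 76 for lists, no alternative reversed the direction of a called gene or of a list test past the threshold. Sign changes of genes not called were not counted as reversals. List medians near 0 could change sign, as for the H3K4 list on day 0 (−0.013, and 0.011 without scramble replicate 1). For genes, 15598 comparisons with an alternative kept their side of the threshold, 300 lost the call and 18 gained one; 208 of the losses, in 47 results, came from leaving out a library. For lists, 1136 kept it and 134 lost the call, 67 with the estimated correlation, 53 without a library, 9 with fry and 5 with no filter.

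With the replicate number as a block the counts were 2679, 4195, 4148, 10584 and 1824. The numbers do not pair the libraries: libraries of the same number and day had correlated residuals of −0.22 to 0.3, over 0.1 in 1, 1 and 2 of 5 pairs, and 7 of 30 libraries correlated best with one of their own number.

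Depth limits the genes with few reads: 3 reads make up 0.089 to 0.119 CPM by library, the level that a count of 0 allows.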

Other observations

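The tests chosen only after the result was seen were those of the imprinted genes and the comparison of miRNA sites with heptamers of the same GC content. Unless said otherwise, the fold changes and calls of genes in this part come from edgeR on the reads recovered from the CPM table.

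Imprinted genes were looked at because H19 is one. Of 28 symbols 20 were tested, and 3 rose and 4 fell with Kdm5c siRNA on day −2, 3 rose and 8 fell on day −1, and 3 rose and 8 fell on day 0. H19 was already at 0.468 ± 0.14 CPM against 2.36 ± 0.46 on day −1 (log2 fold change −2.31, adjusted p = 2.68e-15, edgeR). Impact, a regulator of the stress kinase GCN2, fell from 77.3 ± 2.2 to 60.9 ± 1.5 CPM on day −2, from 92.9 ± 1.5 to 69.9 ± 3.9 on day −1 and from 123 ± 7 to 98.6 ± 3.1 on day 0 (SD, n = 5). Airn, the non-coding RNA antisense to Igf2r, fell by 0.46 on day −1 and by 0.38 on day 0, while Igf2r fell by 0.10, 0.21 and 0.10 from day −2 to day 0. Mest went from 25.5 ± 3.6 to 17.4 ± 3.2 CPM on day 0, and Sgce rose by 0.20, 0.28 and 0.14. Over the control time course 14 of the 20 rose and 2 fell. Of 391 genes of the X chromosome without Kdm5c, 59, 86 and 80 rose and 18, 55 and 55 fell from day −2 to day 0 in the 12016 genes of the count table. Over all 12016 genes, 1346, 2254 and 2312 rose and 1419, 2014 and 1889 fell, so that 23%, 35.5% and 35% were called. Whether genes of the X chromosome differed from the others was not tested.

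Several genes that the deposited count table left out changed. Lum, for the matrix proteoglycan lumican, stood at 2.3 ± 0.51 against 9.68 ± 2.7 CPM on day 0 (log2 fold change −2.07, adjusted p = 4.61e-08, edgeR). Angptl7 stood at 1.94 ± 0.33 against 0.622 ± 0.1 CPM on day 0. Clca2 was at 0.65 ± 0.037 against 1.92 ± 0.32 CPM on day −1, the chemokine gene Ppbp at 0.254 ± 0.06 against 0.771 ± 0.29 CPM on day −2, and the kidney cotransporter gene Slc12a1 at 0.472 ± 0.12 against 0.189 ± 0.054 CPM on day −2. These genes were picked after their values were seen.

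The 7 lists with few measured members were not tested as sets. Of 40 germline genes 2 had enough reads, and Sycp2, of the synaptonemal complex, fell by 0.95 on day −1 and 0.86 on day 0 (7.58 ± 1.1 to 4.17 ± 0.79 CPM on day 0). Of 15 tested histone genes 1 fell on day 0, Hist1h1c by 0.27. Of 5 macrophage markers Cd68 rose by 0.91 and Csf1r by 0.52 on day 0, and the list summed to 11.8 against 10.5 CPM. In the 12016 genes of the count table the Csf1r call was lost without Kdm5c siRNA replicate 1, 3 or 5 (adjusted p = 0.0961, 0.0866 and 0.0523) or scramble replicate 1, 3 or 5 (0.0752, 0.082 and 0.0749). Of 4 endothelial markers Pecam1 and Vwf rose on day 0, by 0.97 and 0.44, and Kdr rose by 0.62 on day −1, a call lost without scramble replicate 2 in the genes of the count table (adjusted p = 0.051). Of 3 myogenic markers Tnnt2 rose by 0.24, 0.73 and 0.88 from day −2 to day 0. Of 2 epithelial markers none was called by edgeR on any day, and the list summed to 0.538 to 1.21 CPM. Of 7 brown and beige adipocyte markers Ppargc1a and Pdk4 rose by 0.25 and 0.14 on day −2, Ebf2 fell by 0.28 on day −1, and on day 0 Tmem26 rose by 0.71 and Pdk4 fell by 0.19. In the genes of the count table the day −2 call of Ppargc1a was lost without Kdm5c siRNA replicate 4 or scramble replicate 1 or 3 (adjusted p = 0.104, 0.109 and 0.074), and that of Pdk4 without Kdm5c siRNA replicate 3, 4 or 5 or scramble replicate 4 (0.058, 0.087, 0.0767 and 0.114).

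A further hypothesis was that the transfected siRNA, by occupying the silencing machinery, relieves genes from the cell's own miRNAs. The median score of 26 sites of 13 miRNA families other than miR-29 and let-7 was 1.22 on day −2 in the fit of the 12016 genes of the count table, above the 95th percentile of 0.48 in 10000 random sets of heptamers. It also lay above the 95th percentile of 0.64 and the highest value of 1.21 in sets of the same GC content. The sites of a family overlap in sequence and the random sets held no such pairs, so their medians may vary too little. Scores were negative for miR-22 (−1.14 and −0.66), miR-125 (−0.12 and −0.75) and a single site each of miR-24, miR-27 and miR-103. Both sites of the other families scored positive. Sites of miR-29 scored 5.06 and 5.69 and those of let-7 2.89 and 3.47. The miR-29 sites ranked 1 and 2 among the heptamers of day −2, and a let-7 site ranked 2 on day −1. The hypothesis may therefore have been drawn from the same scores that then tested it. Weaker repression by endogenous miRNAs in the Kdm5c siRNA cells may thus have raised part of the transcripts on day −2, but both arms received 50 nM of siRNA, and whether they differ in how they load the machinery was not tested. Heptamers made mostly of A and T, of no listed family, also scored high on day −2: TGTTATA 4.41, CAAATAT 4.31 and TATTTAT 4.29. A difference linked with such heptamers was not separated from weaker miRNA repression, beyond the matching on GC content.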
